A study of Mus musculus with 13 samples.

How the data were processed

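Total RNA of cells sorted magnetically on Pdgfra from mouse brain, to enrich OPCs, was sequenced after library preparation with a low-input stranded total RNA kit, in 13 libraries at 4 ages. Myelin removal beads were used at P80 and P310 and not at E16 or P12, per the labels. Samples were grouped by the age in their titles, while the age field of the labels gives 81 days for 2 of the P80 samples and 306 to 308 days for the P310 samples. Per the file headers, the deposited values are raw counts per gene made with featureCounts 1.5.0-p1 on exons of an Ensembl GRCm38 release 92 annotation. The authors counted reads that overlap several genes and reads that map to several places for each gene, with a minimum overlap of 10 bases and no strand option, so paralogs and overlapping genes share reads. Trimming with Trim Galore and alignment with TopHat2 2.1.1 to the mouse genome are named in the labels. Whole numbers with totals that differ between libraries were checked in each file.

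The 13 files held the same 37785 genes in the same order, of which 37715 were named from the GENCODE M21 annotation and 70 kept their identifier. Totals ranged from 8669521 to 25810455 counts per library. The spread between replicates was checked on coding genes with at least 20 counts in a pair, by the squared difference relative to counting noise. P12 replicates 2 and 3 differed far less than any other pair (2.27 against at least 15.2) and their counts were summed into 1 sample, called P12 replicate 2-3, a choice made after seeing the data. This left 3, 2, 3 and 4 samples at E16, P12, P80 and P310.

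Genes were kept with filterByExpr by age and scaled by TMM, and a model with a mean per age was fitted to all 12 samples in edgeR 4.0.16 (robust quasi-likelihood F test) under R 4.3.3. The common biological coefficient of variation was 0.513. The 3 successive ages were compared, and all ages together, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Gene lists, 35 in all and 11 of them markers of other cell types, were tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Summed CPM of lists was compared with exact two-sided permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for summaries and figures. The lists, the comparisons of ages, the list tests and the rule for named genes were set before the data were examined. Sums of lists other than those of other cell types were added afterwards, as were the tests marked below as chosen after the result was seen.

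The rule names, per comparison, the 6 largest rises and 6 largest falls among called coding genes with a mean of at least 10 CPM in the higher group and no overlap between groups, up to 3 members with the smallest adjusted p of each list described (4 for channels and receptors) and members that go against a list, and always Pdgfra, Cspg4, Olig2, Sox10, Mbp and Mki67. For all ages together it names the 6 genes with the smallest adjusted p. Where fewer members of a list are named than the rule allows, those named were chosen after their values under the alternatives were seen. Where a gene had no count in a whole group, its fold is a bound against 3 counts over that group. Such a bound uses the mean of the other group and does not cover the spread between its samples.

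The alternatives tried were size factors by RLE and upper quartile, no low-count filter and a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with quality weights, only the 2 ages compared, a term for the replicate number, counts without mitochondrial, ribosomal and haemoglobin genes, a log2 change of at least 1, a test against a 1.5-fold change, and leaving out each replicate in turn. P12 replicates 2 and 3 kept apart, and leaving out the 2 libraries highest in myelin genes, were added after seeing the data. The procedure was tested on simulated data with 200 changed genes per comparison, where 4-fold changes were called for 19%, 15% and 28% of genes in the 3 comparisons, with at most 2 false calls. These rates hold for that number of changed genes, and more changed genes make the adjustment less strict. No sequence reads were used here, and the values of some genes are not reported here.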

Results

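Oligodendrocyte precursor cells (OPCs), the glial progenitors from which myelin-forming oligodendrocytes arise, were to be enriched from the brains of C57BL/6 mice with magnetic beads against Pdgfra, and total RNA of the sorted cells was sequenced in 13 bulk libraries. The libraries fell into 4 ages, E16 (embryonic, 3 libraries), P12 (early postnatal, 3), P80 (young adult, 3) and P310 (older adult, 4). The E16 libraries held 12581355, 14866649 and 14621771 gene counts. The P12 libraries held 14613236, 17590193 and 25810455, and the P80 libraries 13565319, 8809017 and 14104843. The P310 libraries held 8669521, 14420096, 11429221 and 11950230. A gene with no count in a library is compatible with up to 3 counts, which is a CPM (counts scaled to a common library total) of 0.116 in the deepest and 0.346 CPM in the shallowest library. Such limits cover counting error only, since PCR copies are not independent molecules. Values below are TMM-scaled CPM as mean ± SD over samples, and fold changes are on the log2 scale. After the low-count filter 21170 genes were tested.

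P12 replicates 2 and 3 differed by little more than counting noise, with a chi-square per degree of freedom of 2.27 over 15584 genes, while the other 14 pairs of libraries of the same age gave 15.2 to 179. Their counts were summed, which left 12 samples and n = 2 at P12. Along the first principal component, which held 79.5% of the variance of the 1000 most variable genes, the E16 samples lay at -126.93 to -121.49 and all other samples at 6.85 to 54.74. Mitochondrial transcripts took from 1.52% of the counts in E16 replicate 1 to 34.4% in P310 replicate 1. Xist, the transcript of the inactive X chromosome, and the Y-linked Ddx3y and Eif2s3y were both present in all E16 libraries and in P12 replicate 1. Libraries with both may hold cells of more than 1 mouse, so n may not count single mice there. P12 replicates 2 and 3 had 1.08 and 1.47 CPM of Xist with 965 and 1363 counts of Ddx3y. The 2 P12 samples thus also differ in sex-linked transcripts, and leaving out 1 of them changes that too. The 7 adult libraries had 267 to 825 CPM of Xist (of raw totals), 0 counts of Eif2s3y and 1 count of Ddx3y in all. In the same adult libraries the Y-linked Uty had 457 to 984 counts and Kdm5d 54 to 164. The near absence of Ddx3y and Eif2s3y argues against a Y chromosome as the source of those reads. Where they came from instead could not be told from counts per gene. The sum of these 4 Y-linked genes was 42.8 to 84.5 CPM (of raw totals) in the adult libraries, 62.5 to 81.8 at E16, 73.3 in P12 replicate 1, and 201 and 187 in P12 replicates 2 and 3. In the adult libraries this sum rests on Uty and Kdm5d, so it does not tell the sexes apart.

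The bead target Pdgfra (ENSMUSG00000029231, GRCm38 chromosome 5, 75152292 to 75198215) stood at 33.0 ± 6.96 CPM at E16 (n = 3), 70.1 ± 33.2 at P12 (n = 2), 37.1 ± 18.4 at P80 (n = 3) and 30.7 ± 25.8 at P310 (n = 4). None of its 3 steps passed the test (adjusted p = 0.242, 0.772 and 0.970), though 3 of 26 alternatives called the step from E16 to P12. The summed CPM of 20 OPC identity genes was 1260 ± 138, 836 ± 125, 454 ± 30.01 and 435 ± 135 at the 4 ages in order. Over the same ages the sum of 16 endothelial markers was 116 ± 5.61, 6894 ± 1414, 8287 ± 838 and 8572 ± 2187. The astrocyte sum was 540 ± 44.6, 3554 ± 492, 1876 ± 436 and 1266 ± 403, and the microglia sum was 224 ± 20.3, 1418 ± 45.0, 1246 ± 657 and 1040 ± 573. The immature neuron sum was 8143 ± 770 at E16 and 365 ± 39.7, 145 ± 19.2 and 222 ± 96.4 afterwards. The immature neuron sum at E16 and the endothelial sum at the later ages were thus larger than that of the OPC identity genes. From E16 to P12 the OPC identity sum fell, while the median log2 change of its members was 0.80, with 3 called up and 4 called down. Pdgfra, Cspg4, Olig2 and Sox10 changed by 1.09, 2.13, 1.27 and 3.16, of which only Cspg4 passed the test. Pdgfra is also a member of the fibroblast list. Sums over different genes are not cell shares, but the values below are those of a mixed fraction. Exact two-sided permutation tests of such sums cannot go below p = 0.2 for P12 vs E16 and P80 vs P12, or 0.0571 for P310 vs P80.

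**Figure D1:**
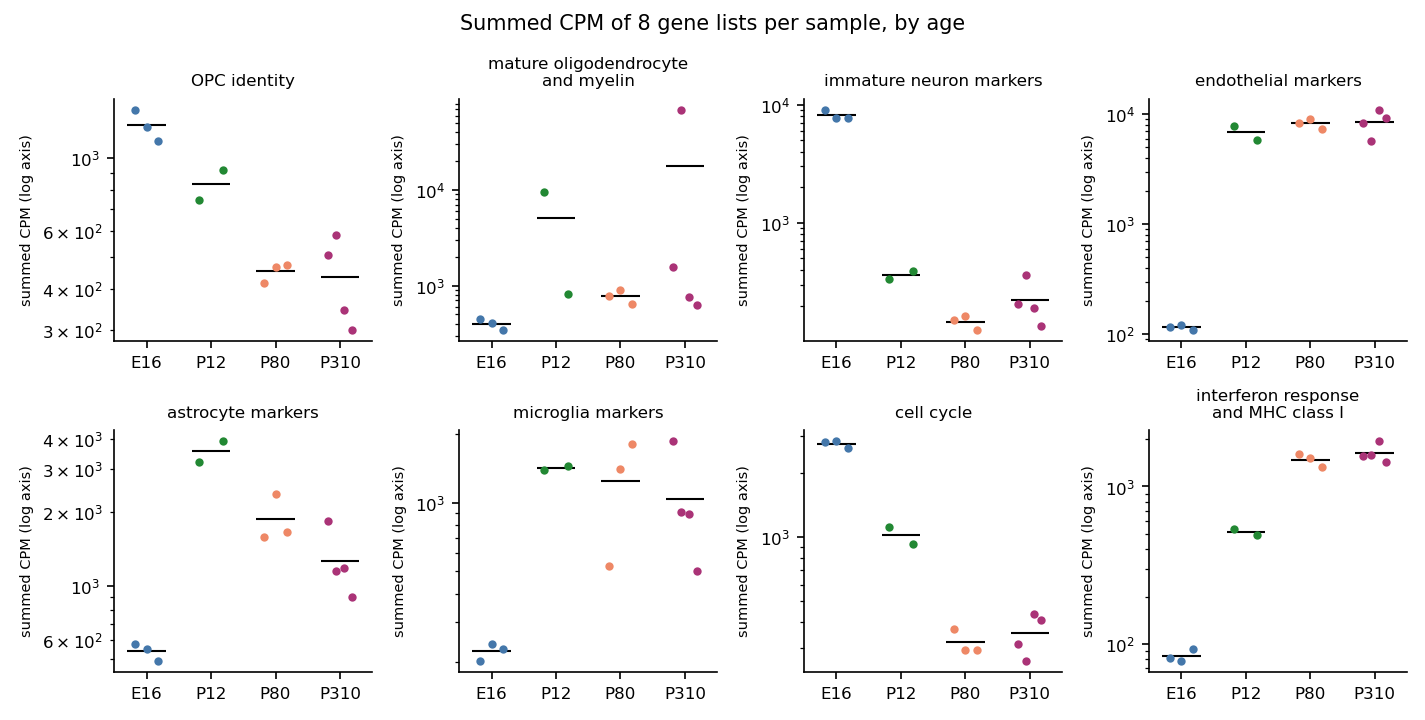
Summed TMM-scaled CPM (log axis) of 8 gene lists against age, with a point per sample and a line at each mean. The endothelial sum is 110 to 121 in the E16 samples and at least 5729 in every later sample, the immature neuron sum is at least 7653 at E16 and at most 394 later, and the myelin sum reaches 68701 in P310 replicate 2.

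The step from E16 to P12 addresses how the enriched cells of the late embryo differ from those of the early postnatal brain. Genes of immature neurons fell together. Of 18 measured, 16 fell and none rose (17 fell adjusted over the list alone), with a median log2 change of -4.51. Dcx, a microtubule-associated protein of migrating neurons, fell from 916 ± 134 CPM (n = 3) to 23.0 ± 8.76 (n = 2), a log2 change of -5.31. The transcription factor Sox11 fell from 2466 ± 423 to 44.8 ± 6.08 (-5.78), and Sox4 from 1213 ± 160 to 130 ± 27.0 (-3.22). The list had an adjusted p of 5.79e-12 with the preset correlation, and an adjusted p = 0.0553 with an estimated correlation. Of 19 forebrain patterning factors, 11 fell and none rose (11 adjusted over the list alone), with a median of -2.59 and an adjusted p = 0.0421 with an estimated correlation. Among them Fezf2, a regulator of deep-layer cortical neurons, changed by -5.99 (-6.839 to -5.535 over fits without 1 replicate), Lhx2 by -4.41 and Nr2f1 by -2.58. The largest falls among expressed coding genes included 4 neural transcription factors, Neurod6 (371 ± 35.6 to 1.13 ± 0.804 CPM, -8.26), Sox14 (-7.49), Pax7 (-7.11) and Neurog2 (-6.77). The others were the embryonic globins Hba-x (-9.96) and Hbb-y (-7.74). Over fits without 1 replicate, Neurod6 ranged from -9.35 to -7.76, Sox14 from -10.18 to -6.92, Pax7 from -10.48 to -6.47, Hba-x from -12.06 to -9.19 and Hbb-y from -9.24 to -7.23. The immature neuron median ranged from -5.66 (without P12 replicate 2-3) to -3.89 (without P12 replicate 1).

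Other neural and progenitor groups were also tested between E16 and P12. Of 16 mature neuron markers 4 fell and none rose (4 adjusted over the list alone), with Slc17a6, a vesicular glutamate transporter, at -4.58 (-6.02 without P12 replicate 2-3). The summed CPM of these markers was 73.7 in P12 replicate 1 and 2442 in P12 replicate 2-3, against 716 to 816 at E16, so its mean was higher at P12 while the list's median was lower. That list's median was -1.71, or -3.58 without P12 replicate 2-3 and -0.94 without P12 replicate 1, where its call ended (adjusted p = 0.120, range over alternatives 1.19e-05 to 0.518), and its adjusted p = 0.518 with an estimated correlation. Of 14 radial glia and progenitor markers 5 fell and 3 rose (6 and 3 adjusted over the list alone). Eomes, a marker of intermediate progenitors, changed by -5.89 (-7.05 without P12 replicate 2-3), Sox1 by -2.25 and Prom1 by 1.85. Of 12 hindbrain and spinal factors 3 fell and 1 rose (3 and 1 adjusted over the list alone). Of 28 axon guidance and migration receptors 14 fell and 4 rose (15 and 4 adjusted over the list alone), with a median of -1.42 and an adjusted p = 0.264 with an estimated correlation. Plxnd1 and Unc5b, which act in vessels as well as axons, rose by 3.41 and 2.75, against the list. Neither of the lists of progenitor markers and hindbrain factors passed the camera list test (adjusted p = 0.185 and 0.0567), while both passed with fry (adjusted p = 0.0146 and 0.00485).

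Markers of blood vessels and glia were higher at P12. All 16 endothelial markers rose (16 adjusted over the list alone), with a median of 6.72 and an adjusted p = 0.0647 with an estimated correlation. Flt1, a VEGF receptor, went from 4.76 ± 0.847 CPM at E16 to 1048 ± 253 at P12 (7.78), Tek, an angiopoietin receptor, from 2.45 ± 0.457 to 368 ± 40.8 (7.23), and Pecam1, an endothelial adhesion molecule, from 4.98 ± 0.713 to 468 ± 29.1 (6.55). Of 13 mural markers 10 rose (10 adjusted over the list alone), with Myh11, a smooth muscle myosin, at 6.30 (list adjusted p = 0.330 with an estimated correlation). Of 16 astrocyte markers 12 rose (13 adjusted over the list alone), with the water channel Aqp4 at 7.67 and Gfap at 8.25, or 9.33 without E16 replicate 1 (list adjusted p = 0.103 with an estimated correlation). Of 18 microglia markers 15 rose (16 adjusted over the list alone), with Tmem119 at 4.69 and P2ry12 at 4.60 (list adjusted p = 0.473 with an estimated correlation). Of 15 ependymal and choroid plexus markers 12 rose (13 adjusted over the list alone), with Ccdc153 at 9.84, or 7.57 without P12 replicate 1 and 11.69 without E16 replicate 3, and a list median of 3.20 (adjusted p = 0.506 with an estimated correlation). The median was 3.99 without P12 replicate 2-3, and without P12 replicate 1 it was 1.40 and the call ended (adjusted p = 0.0787, range 2.03e-07 to 0.506). Of 13 border macrophage and leukocyte markers 5 rose (5 adjusted over the list alone), with Ly6c2 at 4.73. Of 14 fibroblast markers 3 rose (2 adjusted over the list alone), with Col1a2 at 1.66, and of 11 erythroid genes 2 fell (2 adjusted over the list alone), the embryonic globins named above. The last 3 lists did not pass the camera list test (adjusted p = 0.0832, 0.235 and 0.428). With fry their adjusted p was 0.00241, 0.163 and 0.175. None of these lists had a called member against its direction.

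The lists of the oligodendrocyte lineage were each tested between E16 and P12, but not against each other. Of 20 OPC identity genes 3 rose and 4 fell (3 and 4 adjusted over the list alone), and the list did not pass its test (adjusted p = 0.795), with a positive median of 0.80 while the test pointed down. Cspg4 (NG2), a proteoglycan of OPCs and pericytes, rose from 13.6 ± 5.89 to 59.6 ± 7.53 CPM (2.13, adjusted p = 2.77e-04). The transcription factors Sox5 and Sox6 fell by 3.26 and by 2.08, and the proteoglycan Vcan fell by 2.82. Of 15 genes of committed precursors 6 rose and 4 fell (7 and 4 adjusted over the list alone), among the former Gpr17, a receptor of cells about to differentiate, from 2.36 ± 1.21 to 47.3 ± 15.5 CPM (4.31). Enpp6, an enzyme of newly forming oligodendrocytes, had no count at E16 and 19.6 ± 7.23 CPM at P12, at least 311-fold higher. Of 26 mature oligodendrocyte and myelin genes 13 rose and none fell (14 adjusted over the list alone), with the myelin protein Mal at 7.95 and Tspan2 at 5.71. Without P12 replicate 1 they were 6.57 and 4.20, Mal was 9.17 without E16 replicate 3, and Tspan2 was 6.43 without P12 replicate 2-3. The myelin sum was 9401 CPM in P12 replicate 1 and 818 in the other P12 sample, and Mbp, encoding myelin basic protein, stood at 14.5 ± 3.71 CPM at E16 and 1756 ± 2322 at P12 (adjusted p = 0.112). The myelin list's median of 4.97 (4.42 with genes at 0 set to their bound) was 5.95 without P12 replicate 2-3 and 2.23 without P12 replicate 1, where its call ended (adjusted p = 0.0787, range 5.96e-09 to 0.518). Its adjusted p = 0.518 with an estimated correlation. Olig2 stood at 5.86 ± 1.58 and 14.2 ± 2.29 CPM (adjusted p = 0.456), and Sox10 at 3.43 ± 1.61 and 31.0 ± 20.8 (adjusted p = 0.113). Among the alternatives, 2 of 26 called Olig2, 5 of 26 called Sox10 and 4 of 25 called Mbp.

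**Figure D2:**
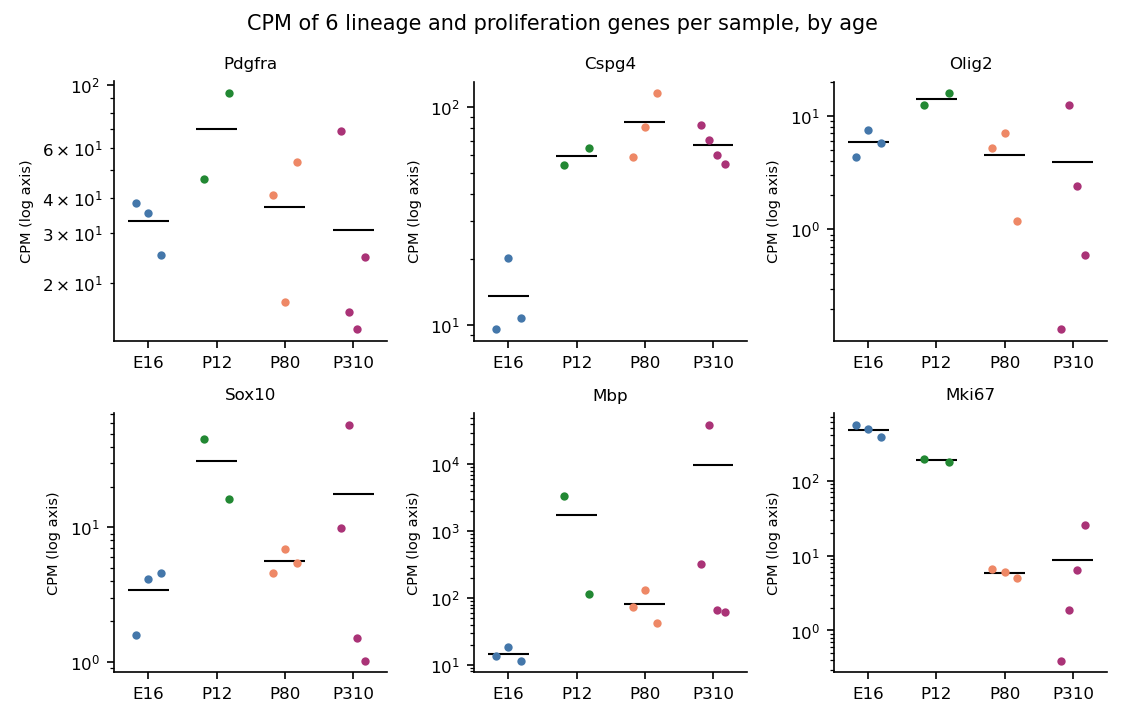
TMM-scaled CPM (log axis) of 6 genes against age, with a point per sample and a line at each mean. Mki67 lies between 382 and 556 CPM at E16 and at no more than 25.8 in the adult samples, and Mbp in P310 replicate 2 is 39223 CPM against at most 319 in the other P310 samples.

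Cell cycle genes fell between E16 and P12 in part. Of 36 measured, 13 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -1.58 and an adjusted p = 0.319 with an estimated correlation. Mcm7, part of the replicative helicase, fell from 107 ± 7.87 to 22.8 ± 4.31 CPM (-2.23) and the cyclin Ccnd2 from 376 ± 52.6 to 127 ± 6.42 (-1.57). The cyclin Ccnd1 rose by 1.87. Mki67, a proliferation marker, stood at 475 ± 87.3 and 187 ± 13.99 CPM (adjusted p = 0.403, called in 3 of 26 alternatives). Of 7 cyclin-dependent kinase inhibitors Cdkn1a and Cdkn2b rose, by 3.60 and 7.76 (the latter 7.01 to 10.39 over fits without 1 replicate), and 2 fell, Cdkn1b among them at -1.60 (2 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.771).

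Interferon response genes were higher at P12, and genes of signalling pathways went both ways. Of 26 interferon response and MHC class I genes 23 rose and none fell (24 adjusted over the list alone), with a median of 3.02 and an adjusted p = 0.0527 with an estimated correlation. The class I gene H2-K1 went from 4.02 ± 0.911 to 52.7 ± 0.0537 CPM (3.71), the peptide transporter Tap2 changed by 5.45 and the RNA sensor Ddx58 by 4.30. Of 22 inflammation genes 10 rose and 2 fell (11 and 3 adjusted over the list alone), with Igfbp7 at 5.55 and the chemokine Cxcl12 at 3.67 (list adjusted p = 0.330 with an estimated correlation). Mmp9 (-3.49) and Ccl3 (-2.85) fell, against the list. The call of Mmp9 ended without E16 replicate 2 (-3.20), P12 replicate 1 (-3.70) and P12 replicate 2-3 (-3.29), and that of Ccl3 without E16 replicate 3 (-2.13) and P12 replicate 2-3 (-2.12), while it was -4.08 without P12 replicate 1. Of 18 BMP pathway genes 9 rose and Id4 fell (10 and 2 adjusted over the list alone), with the targets Id1 at 4.25 and Smad6 at 3.48 (list adjusted p = 0.319 with an estimated correlation). Id4 was -1.60, and -1.33 without P12 replicate 2-3, where its call ended. Of 18 Notch pathway genes 9 rose and 3 fell (10 and 3 adjusted over the list alone), with the ligands Jag2 and Dll4 at 3.98 and 4.84 and the target Hes5 at -3.30. The Notch list had an adjusted p = 0.492 with an estimated correlation. Its call ended in 5 of 24 alternatives, among them the fits without P12 replicate 1 (median 0.91) and without P310 replicate 2 (median 0.89). Of 24 Wnt pathway genes 11 rose and 3 fell (13 and 4 adjusted over the list alone), with Apcdd1, a Wnt inhibitor expressed in brain endothelium, at 3.89. The Wnt list did not pass with camera (adjusted p = 0.0715) but did with fry (adjusted p = 6.73e-04). Of 24 cholesterol synthesis genes 5 fell and Stard4 rose (4 and 1 adjusted over the list alone), with the regulator Srebf2 at -1.01 (list adjusted p = 0.511 with an estimated correlation). That list's call ended without E16 replicate 3 (median -0.37) and without P12 replicate 2-3 (median -0.15), and the call of Stard4 ended without P12 replicate 1 (0.98). The largest rises among expressed coding genes were all of genes with no count at E16. By the P12 mean, Agt (angiotensinogen) was at least 794-fold higher, the transporter Slc47a1 478-fold and the nitric oxide synthase Nos2 451-fold. Meox1 was at least 265-fold and the kinase Musk 251-fold higher by that mean. The floor was 3 counts over the E16 group, and the spread between the P12 samples is not covered. Nos2 stood at 28.5 ± 13.9 CPM at P12 and Meox1 at 16.8 ± 8.57. Their log2 changes were 11.2 to 11.95 and 10.4 to 11.2 over fits without 1 replicate. Musk stood at 15.9 ± 17.6 CPM at P12 (28.3 in P12 replicate 1 and 3.46 in P12 replicate 2-3), a log2 change of 10.96, or 8.77 without P12 replicate 1. Of 22 dissociation and immediate early genes 9 rose and Hspa8 fell (9 and 1 adjusted over the list alone), with Klf2 at 5.88 (list adjusted p = 0.635 with an estimated correlation). That call ended without E16 replicate 2 (median 0.67) and P12 replicate 1 (median 0.72), and the call of Hspa8 (-1.17) ended without P12 replicate 2-3 (-0.86). Of 13 mitochondrial protein genes 10 rose (13 adjusted over the list alone), with a median of 1.69 (0.89 without P12 replicate 2-3, 2.23 without P12 replicate 1) and an adjusted p = 0.521 with an estimated correlation.

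Ion channels and transmitter receptors changed gene by gene, and several of their sums, like that of mature neuron markers (73.7 and 2442 CPM), differed between P12 replicate 1 and P12 replicate 2-3. The sums were 50.6 and 228 CPM for sodium channels, 204 and 458 for voltage-gated potassium channels, 223 and 1005 for calcium channels and 159 and 560 for AMPA and kainate receptors. They were 54.5 and 321 for NMDA receptors, 40.1 and 125 for metabotropic receptors and 49.5 and 137 for GABA-A receptors, and 280 and 277 for inward rectifier and tandem-pore channels. Of 19 inward rectifier and tandem-pore potassium channels 5 rose and 1 fell (5 and 1 adjusted over the list alone), with Kcnj2 from 1.41 ± 0.441 to 49.4 ± 19.3 CPM (5.13), Kcnk1 at 3.19, Kcnj16 at 2.56 and Kcnk6 at 3.36. Of 13 voltage-gated sodium channel genes 2 rose, Scn4b (4.05, or 2.72 without P12 replicate 2-3 and 4.72 without P12 replicate 1) among them, and Scn3b (34.3 to 8.56 CPM) and Scn3a fell (2 and 2 adjusted over the list alone). Scn3a was -2.56, and -3.90 without P12 replicate 2-3 and -1.89 without P12 replicate 1, where its call ended. Of 30 voltage-gated potassium channel genes 4 rose and 2 fell (4 and 1 adjusted over the list alone). Among them Kcnd3 was -1.60, and -1.49 without P12 replicate 1, where its call ended. Of 17 calcium channel genes 3 fell (2 adjusted over the list alone), with the subunit Cacnb3 from 132 ± 19.8 to 17.8 ± 11.7 CPM (-2.89, or -3.80 to -2.34 over fits without 1 replicate). Of 21 AMPA and kainate receptor genes 3 fell (3 adjusted over the list alone), with the auxiliary subunits Cnih2 at -3.76 and Cacng4 at -2.42. Over fits without 1 replicate Cnih2 ranged from -4.695 to -3.22 and Cacng4 from -3.24 to -1.91. The AMPA and kainate list was tested as a whole as well. That list's median was -1.03, and -2.19 without P12 replicate 2-3 and -0.29 without P12 replicate 1, where its call ended (adjusted p = 0.119, range 1.19e-05 to 0.518), and its adjusted p = 0.518 with an estimated correlation. Of 7 NMDA receptor genes 2 rose (2 adjusted over the list alone), with Grin2c at 5.81 (4.66 without P12 replicate 2-3), and of 7 metabotropic glutamate receptors 1 rose (1 adjusted over the list alone), Grm3 at 2.74. Of 15 GABA-A receptor genes 2 rose and 1 fell (2 and 1 adjusted over the list alone). Apart from the AMPA and kainate list, no channel or receptor list passed its camera test (lowest adjusted p = 0.0792). With fry the order was reversed, with an adjusted p of 0.0146 for the inward rectifier and tandem-pore list and 0.114 for the AMPA and kainate list.

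Over all genes, 3543 were higher and 2222 lower at P12 than at E16, 27.2% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05). The 2 groups did not overlap for 61.8% of genes, against 20% by chance. The count was 3748 without P12 replicate 2-3 (3599 shared) and 4137 without P12 replicate 1, where the lone P12 sample is assumed to vary like the other groups. The endothelial, glial and neuronal marker sums above changed along with all of these gene groups.

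The step from P12 to P80 compares the early postnatal with the young adult brain, and myelin removal beads were used at P80 and not at P12, so that age and this step cannot be separated. The P80 libraries also had 0 counts of the Y-linked Ddx3y and Eif2s3y, which every P12 library held. Sex is thus not told apart from age either, which bears on the falls of these 2 genes below. Interferon response and MHC class I genes were higher at P80. Of 26 measured, 8 rose and none fell (24 adjusted over the list alone), with a median of 1.76 and an adjusted p = 0.00623 with an estimated correlation. H2-K1 rose from 52.7 ± 0.0537 CPM at P12 (n = 2) to 212 ± 23.6 at P80 (n = 3), a log2 change of 2.01. The interferon-induced Ifit3 rose from 2.83 ± 0.920 to 38.6 ± 16.9 CPM (3.75), a call that ended without P12 replicate 1 (3.47). The largest rises among expressed coding genes also held the interferon-inducible GTPases Tgtp1 (2.66 ± 0.373 to 30.1 ± 0.962 CPM) and Tgtp2 (3.57), near-identical genes that share reads, and the class II gene H2-Eb1 (3.95). The others were Xdh, encoding xanthine dehydrogenase, from 3.97 ± 0.545 to 111 ± 26.1 CPM, and the monooxygenase Fmo2 (4.55). The call of Fmo2 ended without P12 replicate 1 (3.72), P80 replicate 1 (4.49) and P80 replicate 2 (4.43), and its log2 change was 8.29 without P12 replicate 2-3. The call of H2-Eb1 ended without E16 replicate 1 (3.95), P12 replicate 1 (3.25), P12 replicate 2 (3.70) and P80 replicate 3 (3.31), and it was 5.93 without P12 replicate 2-3. The sums of endothelial, mural and microglia markers differed between P12 and P80 by 0.28, 0.24 and -0.36 on the log2 scale. Larger differences over the same step included those of the mitochondrial (1.96), dissociation (1.10), erythroid (-2.09), fibroblast (-1.60), immature neuron (-1.34) and astrocyte (-0.94) sums. The median log2 changes of the members of these lists were 1.79, 1.28, -1.62, -0.90, -1.82 and -0.54, in the same order.

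Cell cycle genes were lower at P80. Of 36 measured, 12 fell and none rose (28 adjusted over the list alone), with a median of -2.64 and an adjusted p = 0.0344 with an estimated correlation. Top2a, the topoisomerase of dividing cells, fell from 66.7 ± 2.63 CPM to 4.17 ± 1.94 (-4.00). The mitotic kinase Cdk1 had 10.4 ± 3.44 CPM at P12 and no count at P80, at least 133-fold lower, and the checkpoint kinase Bub1 had 5.46 ± 1.69 CPM and no count. Mki67 stood at 187 ± 13.99 and 5.88 ± 0.739 CPM, a log2 difference of -4.99 that did not pass the test (adjusted p = 0.0835, range over alternatives 4.42e-42 to 0.376). Of the other largest falls, the histone genes Hist1h3b and Hist1h1b were -5.05 and -6.03, the chemokine receptor Ackr2 -8.15, and the Y-linked Ddx3y and Eif2s3y at least 424-fold and 160-fold lower. These 2 bounds rest on 33.3 ± 22.8 and 12.5 ± 10.4 CPM at P12, and the log2 changes of -12.03 and -10.63 were -10.79 and -9.06 without P12 replicate 2-3. The call of Hist1h1b ended without each E16 library (-6.04, -6.04 and -6.03), P12 replicate 1 (-5.55), P80 replicate 2 (-5.76) and P80 replicate 3 (-5.45), and it was -7.90 without P80 replicate 1. The call of Ackr2 ended without P12 replicate 1 (-7.55), P12 replicate 2-3 (-8.56) and each P80 library (-11.02, -7.82 and -7.52). The OPC identity, immature neuron, fibroblast and erythroid sums were also lower at P80, by log2 differences of -0.88, -1.34, -1.60 and -2.09. With the median log2 CPM of each list in place of its sum they were -1.25, -1.32, -0.67 and -1.45.

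**Figure D3:**
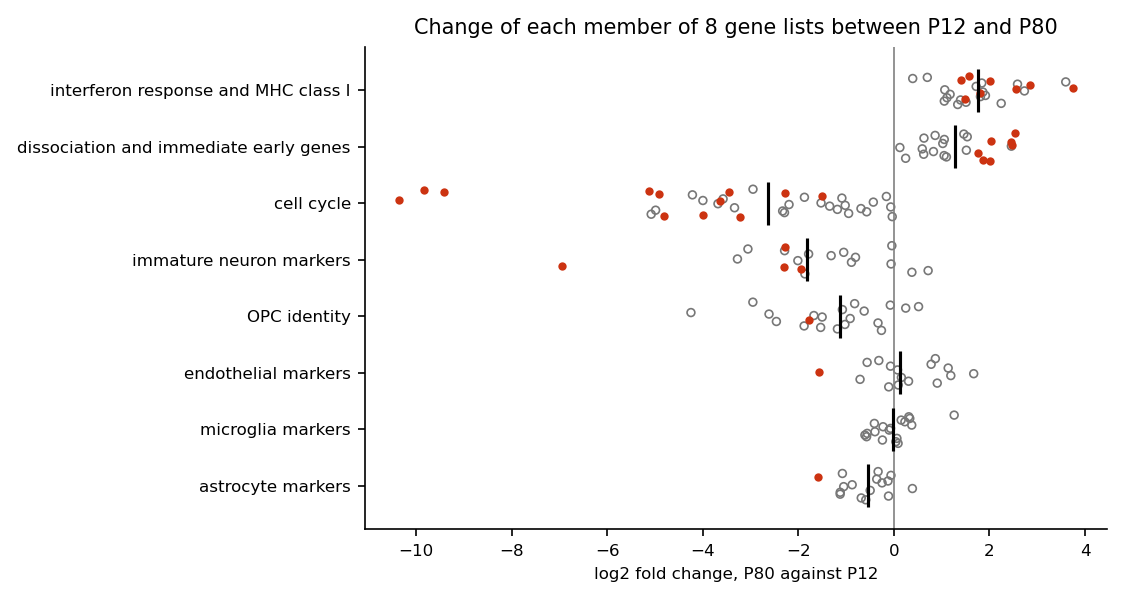
Log2 fold change from P12 to P80 (horizontal axis) of each measured member of 8 gene lists, with filled points for genes past an adjusted p of 0.05 and a bar at each list's median. The medians are 1.76 for interferon response and MHC class I genes, 1.28 for dissociation and immediate early genes, -2.64 for cell cycle genes and 0.12 for endothelial markers.

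Genes of the early oligodendrocyte lineage were lower at P80 as lists by the preset test, by amounts that depended on the P12 sample, with few single genes past the test. Of 15 committed precursor genes none passed over all genes (4 fell adjusted over the list alone), with a list median of -1.40 (-0.79 without P12 replicate 1, -1.84 without P12 replicate 2-3) and an adjusted p = 0.0344 with an estimated correlation. Of 20 OPC identity genes only Ptprz1, a receptor phosphatase of OPCs, fell, from 279 ± 48.8 CPM by 1.79 on the log2 scale (5 fell adjusted over the list alone). Its call ended without P80 replicate 1 (-1.67), P80 replicate 3 (-1.69) and P12 replicate 2-3 (-1.60), and the list had a median of -1.13 (-1.53 without P12 replicate 1, -0.60 without P12 replicate 2-3) and an adjusted p = 0.306 with an estimated correlation. Cspg4 stood at 59.6 ± 7.53 and 85.2 ± 28.6 CPM (adjusted p = 0.742), Olig2 at 14.2 ± 2.29 and 4.47 ± 3.00 (adjusted p = 0.763), and Sox10 at 31.0 ± 20.8 and 5.63 ± 1.19 (adjusted p = 0.636). None of 26 myelin genes passed (0 adjusted over the list alone), with Mbp at 1756 ± 2322 and 82.1 ± 44.7 CPM (adjusted p = 0.692). The myelin list's median of -2.99 was -0.30 without P12 replicate 1, where the list test also turned to the opposite direction (adjusted p = 0.989, range 9.91e-11 to 0.989), and its adjusted p = 0.580 with an estimated correlation.

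Every other list had at most 7 genes past the test between P12 and P80, though for dissociation and immediate early genes (7 of 22) this was about the share of the interferon genes (8 of 26). Of 18 immature neuron genes 4 fell (7 adjusted over the list alone), with Sox4 from 130 ± 27.0 to 33.9 ± 3.40 CPM (-1.94) and Sox11 at -2.31 (list adjusted p = 0.219 with an estimated correlation). Of 22 dissociation and immediate early genes 7 rose (17 adjusted over the list alone), with a median of 1.28 and an adjusted p = 0.219 with an estimated correlation. Fosb, an immediate early transcription factor, was 2.46, and its call ended without P12 replicate 1 (2.37), P12 replicate 2-3 (2.54), P80 replicate 1 (2.39) and P80 replicate 3 (2.37). No mitochondrial protein gene passed over all genes (13 rose adjusted over the list alone), with a median of 1.79 and an adjusted p = 0.306 with an estimated correlation. Col3a1, a fibrillar collagen of fibroblasts, fell from 467 ± 129 to 73.5 ± 18.1 CPM (-2.67), and Igfbp3, an insulin-like growth factor binding protein, from 290 ± 83.5 to 46.2 ± 11.9 (-2.65). They were the only called members of the fibroblast list (3 fell adjusted over the list alone, list adjusted p = 0.321 with an estimated correlation) and the inflammation list (3 rose and 1 fell adjusted over the list alone). The latter pointed up, with a median of 0.69 and an adjusted p = 0.329 with an estimated correlation. Its call ended in 8 of 24 alternatives, among them the fits without P80 replicate 1 (0.61), P80 replicate 3 (0.61), P310 replicate 2 (0.73) and P12 replicate 2-3 (0.37). Of 16 endothelial markers the VEGF receptor Kdr fell, by 1.57 (4 rose and 1 fell adjusted over the list alone), a call that ended without P12 replicate 1 (-1.29) and P80 replicate 3 (-1.52). None of the voltage-gated channel, potassium rectifier or transmitter receptor genes in the 8 lists passed, over all genes or over the list alone.

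Over all genes, 86 were higher and 215 lower at P80 than at P12, with 2065 at an unadjusted p under 0.05, and the groups did not overlap for 26.6% of genes against 20% by chance. The count fell to 71 without P12 replicate 1 (67 shared), where the lone P12 sample is assumed to vary like the other groups, to 191 without P80 replicate 1, to 151 without P80 replicate 3, and to 169 without the P12 and P310 libraries highest in myelin genes, and rose to 645 with DESeq2 and 490 with limma-voom.

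The step from P80 to P310 compares 2 adult ages prepared with the same myelin removal, and asks how the enriched cells differ between young and older adults. No gene passed the test in either direction (edgeR quasi-likelihood), with 1162 genes at an unadjusted p under 0.05 and groups apart for 4.86% of genes against 5.71% by chance. DESeq2 called 28 genes, 14 in each direction, and limma-voom called 0. Interferon response genes had a median change of -0.01 (0 called adjusted over the list alone), with H2-K1 at 212 ± 23.6 CPM at P80 (n = 3) and 305 ± 52.4 at P310 (n = 4). Cell cycle genes had a median of 0.01, with Mki67 at 5.88 ± 0.739 and 8.61 ± 11.7 CPM (adjusted p = 0.960). Cspg4 stood at 85.2 ± 28.6 and 67.1 ± 12.3 CPM (adjusted p = 0.910) and Olig2 at 4.47 ± 3.00 and 3.92 ± 5.83 (adjusted p = 0.995).

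Of the 35 lists, 8 passed the list test between P80 and P310 with the preset correlation and none with an estimated one or with fry. Astrocyte markers had a median of -0.75 (3 of 16 fell adjusted over the list alone, adjusted p = 0.345 with an estimated correlation). The gap junction gene Gja1 stood at 167 ± 32.7 and 76.1 ± 35.1 CPM, Slc4a4 at 151 ± 3.28 and 80.9 ± 20.9, and Acsbg1 at 42.3 ± 21.7 and 17.5 ± 5.08. Forebrain patterning factors had a median of -0.37 (4 of 19 fell adjusted over the list alone, adjusted p = 0.345 with an estimated correlation). Emx2 stood at 8.53 ± 4.44 and 3.06 ± 1.05 CPM and Fezf2 at 3.31 ± 1.78 and 0.531 ± 0.404, and the call of the list ended without P80 replicate 2 (median -0.41). Dissociation and immediate early genes had a median of -0.42 (2 of 22 fell adjusted over the list alone), with the heat shock gene Hspa8 at 600 ± 83.0 and 339 ± 81.6 CPM and Atf3 at 43.2 ± 7.15 and 14.8 ± 6.15 (list adjusted p = 0.997 with an estimated correlation). Mitochondrial protein genes had a median of 0.72, or 0.42 without P80 replicate 1, where the call ended (adjusted p = 0.997 with an estimated correlation). Myelin genes had a median of 2.95, with Mbp at 82.1 ± 44.7 and 9917 ± 19538 CPM and Sox10 at 5.63 ± 1.19 and 17.6 ± 27.3, both highest in P310 replicate 2. Without that library the myelin median was 0.39 and the list did not pass (adjusted p = 0.519, range 3.39e-06 to 0.997), and its adjusted p = 0.997 with an estimated correlation. The Wnt list had a median of -0.25 and the radial glia list of -0.36 (both adjusted p = 0.420 with an estimated correlation). The radial glia call ended in 7 of 24 alternatives, among them the fits without P80 replicate 2 (-0.20), P310 replicate 2 (-0.23) and P310 replicate 4 (-0.28). The erythroid list had a median of 0.27 (adjusted p = 0.997 with an estimated correlation), a call that ended without P80 replicate 1 (0.00), P80 replicate 2 (0.14) and P310 replicate 1 (-0.27), with 1.32 without P80 replicate 3.

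Across the 4 ages together 7852 genes (37.1%) differed, of which 3714 had their highest mean at E16, 1106 at P12, 1364 at P80 and 1668 at P310. The 6 expressed coding genes with the smallest adjusted p held 3 neuronal genes highest at E16, Sox4, Dcx and Tubb2b, a neuronal tubulin at 1579 ± 265 CPM at E16 and 62.7 ± 1.34, 33.4 ± 14.9 and 19.7 ± 3.84 at the later ages. Ptprb, the vascular endothelial receptor phosphatase, stood at 5.43 ± 0.312, 1969 ± 13.9, 2500 ± 388 and 3018 ± 819 CPM. Gvin1, an interferon-inducible GTPase, stood at 1.08 ± 0.191, 29.8 ± 5.07, 221 ± 4.53 and 215 ± 26.0 CPM, and its close relative Gm4070, with which it shares reads, had 0.970 ± 0.230, 28.3 ± 2.86, 228 ± 2.45 and 219 ± 17.4. The adjusted p of these genes lay between 7.04e-10 and 3.60e-09.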

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

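The tests of oligodendrocyte or myelin material, of a mislabelled sample, of other cell types, of the myelin removal step and of the share of precursor cells were chosen only after the result was seen.

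P310 replicate 2 lay far from the other 3 P310 libraries in 4 of 62 groups of values tested, where chance gives about 3.1 such gaps, though not all in the same library. Its summed CPM of committed precursor genes was 8276 (others 417 to 537) and of myelin genes 68701 (others 619 to 1559). Its Sox10 level was 58.1 CPM (others 1.02 to 9.90) and its Mbp level 39223 CPM (others 61.4 to 319).

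The first pattern is this high myelin signal, which P12 replicate 1 shares. A mislabelled E16 or P12 sample is argued against, since P310 replicate 2 had a summed cell cycle CPM of 261 (the lowest E16 or P12 sample had 928, the other adult samples up to 434). Counts summed over Y-linked genes did not enter this, since P310 replicate 2 had 984 of Uty and 84 of Kdm5d, and the other adult libraries also had both. Ddx3y and Eif2s3y had 0 counts in P310 replicate 2, against at least 186 and 83 in every E16 and P12 library. These values also argue against a mislabelled sample like those libraries, though not against one from females only. That 25 of 26 myelin genes were highest in P310 replicate 2 among P310 libraries, and 25 in P12 replicate 1 at P12, restates the high sum over its members and tests no source. Oligodendrocytes or myelin fragments in these libraries cannot be told apart from a biological difference between the mice, because no independent measure of either was at hand.

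The second pattern is the rise of interferon response and MHC class I genes from P12 to P80. For more endothelial, microglial, mural or other immune cells, the interferon median lay 1.44 above the highest of their 4 medians (0.32, border macrophages and leukocytes). The 95% bootstrap interval of 0.35 to 1.91 resampled list members and not mice, and left out the choice of the highest median. In these samples the interferon genes thus rose by more than those markers. With n = 2 at P12, whether such cells were the whole cause is not decided. Reads shared between paralogs are argued against, since 16 members without a close paralog had a median of 1.44. The myelin removal step cannot be told apart from age, because it was used at P80 and not at P12, and dissociation and immediate early genes had a median of 1.28 over the same step. Age and sex also stay open, as untested.

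The third pattern is the fall of cell cycle genes from P12 to P80. The cell cycle median lay -1.51 from that of the OPC identity list (95% bootstrap interval -2.66 to -0.35, which resampled list members and not mice). In these samples the cell cycle genes thus fell by more than the OPC identity genes. Whether a smaller share of precursor cells was the whole cause is not decided, since the fraction is mixed and P12 had n = 2. With every sample thinned to 8669521 counts the median was -2.43, against -2.41 unthinned. Thinning leaves the expected CPM of a gene unchanged, so this outcome was nearly fixed in advance and does not decide on lower depth. A change in the division of cells in the sorted fraction with age, fewer dividing cells of another type, sex, and the myelin removal step stay open as untested.

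For genes differing between any ages, 1 of 65 groupings of the 12 samples, the real one itself, reached the real count (7852). The highest other gave 1. A share of 1 in 65 is the smallest that this many groupings can give. Random assignment of the samples is argued against to that extent, but age, preparation, sex and the mix of cells are not told apart. The E16 samples lay far from all others along the first principal component, and groupings that mix them with later ages raise the fitted spread. The outcome thus need not bear on differences among P12, P80 and P310. For P310 vs P80 the real count was 0 (edgeR, 1162 genes at an unadjusted p under 0.05, DESeq2 28, limma-voom 0), so all 35 splits of the 7 adult samples reach it by construction and say nothing of chance. The highest other split set P80 replicate 2 and P310 replicates 1 and 2 against the other adult samples and gave 18 genes. Those samples had the largest mitochondrial protein sums of the adults (69306, 1.12e+05 and 1.12e+05 CPM, the others at most 59325). Whether this single split reflects a structure of the samples was not tested.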

How the results depend on the processing

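The fits with P12 replicates 2 and 3 kept as 2 samples, those without the 2 libraries highest in myelin genes, and the alternatives for sums of lists other than cell-type markers were chosen only after the result was seen. Of results for single genes under the alternatives, 4434 kept their direction and side of the threshold, 219 lost a call, 30 gained one and 9 reversed. Of list results 880 kept both, 100 lost the call and 1 reversed. Among these, fry kept 20 list calls and ended 21, and camera with an estimated correlation kept 4 and ended 37. Of summed CPM results 171 moved by less than the spread between replicates and 39 by more, such as fibroblast markers in P80 vs P12 (-1.60, and -0.67 as a median log2 CPM). Leaving out 1 replicate moved the size by more than 1 on the log2 scale for 28 of 134 called genes and 5 of 19 called lists in P12 vs E16, 7 of 30 and 1 of 14 in P80 vs P12, and 2 of 8 lists in P310 vs P80. Where the cause of a change is not given, the cause was not tested.

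Leaving out 1 replicate at a time, the P12 vs E16 count ranged from 3748 (without P12 replicate 2-3) to 6553, that of P80 vs P12 from 71 (without P12 replicate 1) to 446, and that of P310 vs P80 from 0 to 1. For P80 vs P12 it was 877 without the low-count filter, 521 with P12 replicates 2 and 3 kept as 2 samples, 169 without the 2 libraries highest in myelin genes, 645 with DESeq2, 490 with limma-voom and 173 when tested against a 1.5-fold change. For P310 vs P80 (0 in edgeR, 1162 at an unadjusted p under 0.05, limma-voom 0) it was 423 without the filter, 28 with DESeq2 and 1 with the replicate block. Without the filter the fitted spread left no weight to a gene's own variance, and 417 of the 423 genes were also tested with the filter. The single gene under the block and without P310 replicate 4 was H19 (-3.56 and -3.54), named after its values were seen. The count over any age stayed within 1.5 times under every alternative run (5785 to 10849).

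The direction reversed for differences that did not pass the test, for the test of the myelin list in P80 vs P12, and for the median of the erythroid list in P310 vs P80 (0.27, and -0.27 without P310 replicate 1, where its call ended). In P310 vs P80, Pdgfra ranged from -1.04 to 0.0581 (without P80 replicate 3) over fits without 1 replicate, and Olig2 from -2.04 to 0.29 (without P80 replicate 2, with 0.21 without P310 replicate 1 and 0.18 without P310 replicate 4). Sox10 ranged from -0.48 (without P310 replicate 2) to 2.04, with -0.47 without the 2 libraries highest in myelin genes and -1.14 in limma-voom. Mki67 ranged from -0.97 (without P310 replicate 4) to 0.96, with -1.07 under the block. The myelin list in P80 vs P12 had medians from -3.83 to -0.30 (without P12 replicate 1, where its test turned up) over fits without 1 replicate, and -0.20 without the 2 libraries highest in myelin genes, where its call ended. Other scaling moved the median of all genes by at most 0.0774. The fit of only 2 groups was not run for any age difference. Simulated 2-fold changes were called for at most 2% of genes, so the spread and number of samples limit what could be detected. The simulation changed only 200 genes, against 5765 called in P12 vs E16. Fewer changed genes make the adjustment stricter, so the simulated rates do not carry over to that comparison.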

Other observations

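The grouping of genes by the stem of their symbol was chosen only after the result was seen, and 1132 such tests with at least 8 members were run. Replication-dependent histone genes of the Hist1 cluster, which package new DNA in dividing cells, were lower at P12 than at E16 for 48 of 53 members (adjusted p = 3.42e-35) and lower at P80 than at P12 for 40 of 53 (adjusted p = 4.64e-65). Of the Hist2 genes 6 of 10 were lower at P80 (adjusted p = 1.31e-07). These genes share reads, so their members are not independent. The protocadherin alpha genes, neuronal adhesion molecules that share exons, were lower at P12 than at E16 for 12 of 12 (adjusted p = 5.85e-09). A read in their shared exons counts for each of them, so these 12 are not independent and this p overstates the evidence.

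Among genes higher at P12 than at E16 were 26 of 45 collagen genes (adjusted p = 2.49e-06), 19 of 30 Cfap genes of motile cilia (adjusted p = 2.62e-05), 11 of 15 dynein heavy chain genes (adjusted p = 0.00102) and 9 of 10 interferon-inducible guanylate-binding protein genes (adjusted p = 4.10e-04). The guanylate-binding protein genes are paralogs that can share reads, so their members are not independent either. Markers of ependymal cells, which bear motile cilia, and choroid plexus had a summed CPM of 5751 in P12 replicate 1 and 919 in P12 replicate 2-3, against at most 209 at E16. The median of that marker list was 3.20, or 1.40 without P12 replicate 1 and 1.43 without both P12 replicate 1 and P310 replicate 2. Its adjusted p was 0.506 by camera with an estimated correlation. The cilia genes were not tested without P12 replicate 1.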
